A study of Mus musculus with 8 samples.

How the data were processed

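Brown adipose tissue of Prdm16 knockout and wild-type mice was profiled on Agilent 2-colour mouse arrays, 4 arrays for 6-week-old and 4 for 11-month-old mice, per the labels. Each array carried 1 knockout and 1 wild-type sample of the same age, with the dyes exchanged on 2 arrays of each age. The ages were run as separate batches per the labels, and per the file headers each age lay on a slide of its own. Per the file headers, the deposited scanner tables hold mean foreground and median local background intensity per spot and channel as read by Agilent Feature Extraction 10.5.1.1 at 6 weeks and 10.10.1.1 at 11 months, on a design annotated to mouse build mm9. Per the file headers, the same tables hold a log10 ratio of Cy5 over Cy3 after background subtraction and dye normalization by the scanner software. The deposited value table of 43173 entries per array holds log2 ratios, and limma is the tool named in the submitters' processing notes. Its background correction and normalization are not given in the sources used here. Tested against the scanner values, the deposited log2 ratios had correlations of 0.975 to 0.99 in size and a sign that followed the dye of the knockout sample, so they were read as knockout over wild type. They served as an alternative only. Their entry numbers were matched to the running number of the spot in the scanner tables, since the empty cells all fell on spots marked as non-uniform.

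The analysis started from the mean intensities. Background was corrected with the normexp method (offset 50), and log ratios were normalized within each array by loess with control spots and excluded spots at weight 0, in limma 3.58.1 (R 4.3.3, data.table version 1.17.8). Ratios were turned to log2 of knockout over wild type by the dyes in the labels. Spots marked by the scanner software as non-uniform or as population outliers (131 to 247 per array) were left out, and replicate spots of a probe were averaged. Of 39429 probes, 26853 were kept for being well above background in at least 4 of the 16 channel measurements and measured on at least 3 arrays of each age. Signal over background set this limit, and 61.2% to 68.2% of spots per channel lay well above background. Where a gene had several kept probes (4267 genes), the probe with the highest mean log2 intensity stood for it. Of the 21742 genes tested, 14810 took their symbol from a RefSeq table of assembly GRCm38.p6 through the accession on the array, and 6932 kept the name the array gives. No coordinates were taken from that table.

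One limma model of all 8 arrays had a coefficient for each age and a shared dye coefficient, leaving 5 residual degrees of freedom. Standard errors are those of the moderated model, and p-values were adjusted by the Benjamini-Hochberg method over all genes within each comparison. A gene was called at an adjusted p below 0.05. The difference between ages is the 11-month-old minus the 6-week-old coefficient of the same model. Fold changes come from the fitted log2 ratios. The dye coefficient itself passed in 1104 genes. A total of 25 gene lists was tested with camera (preset inter-gene correlation 0.01, and again with an estimated correlation), which compares a list with all other genes, and with fry, whose main p tests whether the genes of a list move on balance in one direction. Adjusted p-values of lists were adjusted over the 25 lists of a comparison. The lists covered brown fat-selective, white fat-selective, beige fat-associated and general adipocyte genes, fatty acid oxidation, tricarboxylic acid cycle, nuclear-encoded respiratory chain, lipogenesis, skeletal muscle, interferon-stimulated, macrophage and myeloid, T and B lymphocyte, endothelial, fibroblast and extracellular matrix, smooth muscle and pericyte, nerve and Schwann cell, erythrocyte, skin and epithelium, cell cycle, integrated stress and amino acid response, endoplasmic reticulum chaperones and heat shock, circadian clock, immediate-early genes, PRDM16 partners and adipose regulators, and X- and Y-linked sex markers. Of the 586 genes measured in any list, 15 stood in more than 1, among them Sdhb and Sdhd in the tricarboxylic acid cycle and the respiratory chain, Cox7a1 and Cox8b in brown fat and the respiratory chain, Cpt1b and Fabp3 in brown fat and fatty acid oxidation, and Psat1 in white fat and the stress response.

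The comparisons, the lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Prdm16; for each comparison the 10 highest and 10 lowest called genes with a gene symbol and one sign in all 4 arrays (for the difference, with no overlap between the ages); up to 4 called members of each list with the largest change, or the 2 with the largest change where fewer than 2 were called; and Ucp1, Cidea, Ppargc1a, Dio2, Elovl3, Cox8b, Lep, Retn, Adipoq and Mecom always. It reached 201 genes, not all of which are given here. Of these, 51 had more than 1 kept probe, and probes of one gene could differ in size of change. Probes were called in opposite directions in 0 of the 51 at 6 weeks and in 1 (Ogdh) at 11 months. Members of a list named without a value where a count was 5 or fewer, and Zic1, Lhx8, Ebf2, Ddx3y, Uty and Eif2s3x, were named after their values were seen. Pairs of genes with near-identical copies, such as Kng1 and Kng2 or Eif2s3x and Eif2s3y, may share probe signal.

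The model was tested on simulated log ratios of 21742 genes with known changes. For the 6-week-old comparison it recovered 97.0% of 100 genes changed by 1 and 99.0% of 100 genes changed by 2 on the log2 scale, with 7.11% of all calls false. For the 11-month-old comparison the shares were 97.0% and 99.0% with 6.22% of calls false, and for the difference 92.0% and 99.0% of 200 genes each with 5.91% of calls false. With no change simulated, limma made 0 calls in each comparison. The simulated noise was independent between genes, and 200 genes were changed per age. In the real arrays genes were correlated (estimated at 0.724 within the respiratory chain list), and 16.2% and 34.7% of genes were called at the 2 ages. The simulated rates may therefore not hold for the real arrays.

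The alternatives were no background subtraction, the scanner software's log10 ratio, median centring in place of loess, the deposited log2 ratios, no filter on dim probes and a filter at 12 of 16 channel measurements, the mean of all probes of a gene, no dye coefficient and a dye coefficient per age, each age modelled alone, each array left out in turn, replicate number as a block, an intensity trend in the variance model, and a fold change of at least 2. A skeletal muscle covariate and a model without the 3 arrays of largest skeletal muscle median in size were added after seeing the data. Processed signals of the scanner software beyond its log ratio were not used here. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.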

Results

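Gene expression was measured in brown adipose tissue of Prdm16 knockout and wild-type mice on 8 2-colour arrays, 4 with tissue of 6-week-old mice and 4 with tissue of 11-month-old mice. Prdm16 encodes a zinc-finger transcriptional regulator known for its part in brown fat identity. Each array set knockout RNA against wild-type RNA of the same age, with the dyes exchanged on 2 of the 4 arrays of each age, and the labels call the arrays biological replicates. Every array carried 43020 non-control spots, of which 61.2% to 68.2% per channel lay well above background, and no spot was saturated. After filtering, 21742 genes were tested. Values below are log2 ratios of knockout over wild type with the standard error of the limma model (n = 4 arrays per age), and the number of arrays limits their precision. Across genes, which are not independent replicates, the dye-adjusted log2 ratios of arrays of the same age correlated at r = 0.481 to 0.676 at 6 weeks and 0.678 to 0.885 at 11 months.

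Prdm16 mRNA was lower in knockout tissue at both ages, by less than 2-fold. Its probe (A_55_P1963547, chromosome 4, 153690254 to 153690313 of mm9) gave log2 ratios of -0.39, 0.06, -1.09 and -0.88 in the arrays labelled 6-week-old replicates 1 to 4. The fitted value was -0.58 ± 0.15 (1.49-fold lower, adjusted p = 0.042). The ratios of the 11-month-old arrays were -0.96, -0.18, -0.44 and -0.42, with a fitted value of -0.50 ± 0.15 (1.42-fold lower, adjusted p = 0.0372). The values of the 2 ages differed by 0.07 ± 0.22 (adjusted p = 0.846). Where the probe lies relative to the deleted part of the gene is not given in the sources used here, so the probe is a weak check of the labels. Before adjustment for dye the knockout channel was not the lower in the array labelled 6-week-old replicate 2. The dye coefficient of the probe was -0.24 (Cy5 over Cy3), and with it removed the array that was not lower was 11-month-old replicate 2 (0.0574, against -0.722 to -0.663 in the others of its age). Across genes 6-week-old array 2 correlated with the other arrays of its age at r = 0.482 to 0.676, and directions are given as the labels give them. Both calls were sensitive to settings and to leaving out single arrays, where fewer arrays remain to make a call. The 6-week-old call ended without 6-week-old array 1, 3 or 4 (adjusted p = 0.154, 0.149 and 0.117) or 11-month-old array 1 or 3 (adjusted p = 0.0571 and 0.0536), and with median centring (-0.42, adjusted p = 0.238). The 11-month-old call ended without 11-month-old array 1, 3 or 4 (adjusted p = 0.155, 0.13 and 0.133) or 6-week-old array 1 or 4 (adjusted p = 0.0523 and 0.0557), and with median centring (-0.27, adjusted p = 0.35).

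The first comparison asked which transcripts changed in brown fat of 6-week-old Prdm16 knockout mice. Genes of fatty acid synthesis rose in knockout tissue, with 19 of 26 measured lipogenesis genes higher and 7 not past the test, and a list median of 1.02. The list's call ended with an estimated correlation (adjusted p = 0.472), and fry gave adjusted p = 0.0158. Scd1 and Scd2, desaturases that make monounsaturated fatty acids, rose by 2.28 ± 0.30 (4.85-fold, adjusted p = 0.00408) and 2.17 ± 0.34 (4.51-fold, adjusted p = 0.00788). Of 24 genes selective for white fat 10 rose and 14 were not past the test. This list's call ended with an estimated correlation too (adjusted p = 0.154), and fry gave adjusted p = 0.00091. Retn of that list, which encodes the adipokine resistin, rose by 2.40 ± 0.12 (5.28-fold, adjusted p = 0.000288). The thermogenic uncoupling protein gene Ucp1 was not called, at 0.13 ± 0.44 (adjusted p = 0.864), and Cidea, a lipid droplet protein gene high in brown fat, stood at -0.0036 ± 0.14 (adjusted p = 0.989). Hlf, a transcription factor gene of the circadian clock, fell by 1.75 ± 0.17 (3.37-fold lower, adjusted p = 0.00172). Its clock list had called members on both sides and was not past camera (adjusted p = 0.923). Camera looks for movement in one direction, so opposite changes can cancel there.

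In all, 3520 genes (16.2%) changed at 6 weeks, 1995 higher and 1525 lower in knockout tissue. A change of at least 2-fold was found in 270 of the higher and 124 of the lower genes. Under median centring of each array the split was 664 higher and 284 lower, or 70.0% higher in place of 56.7%, and the median of all genes moved to 0.07. With the scanner software's log ratio it was 1264 higher and 1014 lower (55.5% higher). Among genes with one sign in all 4 arrays, the largest increases were in Aldh3b2 at 3.57 ± 0.25 (11.9-fold, adjusted p = 0.000744), the fructose transporter gene Slc2a5 (3.28 ± 0.62), the apolipoprotein genes Apoc4 (3.16 ± 0.23) and Apoc2 (2.79 ± 0.15), and Mosc1 (2.84). They were followed by Bmp8b, a signalling ligand made by brown fat (2.65), Ncan (2.61), Serpina3k (2.61), Sorl1 (2.54) and the adenylyl cyclase gene Adcy5 (2.54). The largest decreases were in the cytochrome P450 gene Cyp2b10 at -2.94 ± 0.48 (7.66-fold lower, adjusted p = 0.00907), Gldn (-2.49), Olig1 (-2.45), Slco4a1 (-2.43) and Kcp (-2.30). Next came the guanosine monophosphate reductase gene Gmpr (-2.30 ± 0.18), Snhg11 (-2.29), the kinase gene Sgk2 (-2.27), the transferrin receptor gene Tfrc (-2.24 ± 0.16) and the carbonic anhydrase gene Car14 (-2.19). Leaving out single arrays of the age ended the calls of Slc2a5 (without array 1 or 2), Serpina3k (1, 2 or 3), Gldn (2, 3 or 4) and Olig1 (any of the 4, and 11-month-old array 1, 2 or 4), with adjusted p between 0.0543 and 0.184.

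The brown fat-selective list split by gene at 6 weeks. Of 39 measured members 4 rose, 8 fell and 27 were not past the test, or 6 and 9 when adjusted over the list alone, and the median was -0.31 (camera adjusted p = 0.0713). Kng2 and Kng1, kininogen genes whose probes may read both transcripts, fell by 1.94 ± 0.11 (adjusted p = 0.000462) and 1.80 ± 0.19 (adjusted p = 0.00231) on the log2 scale. With the scanner software's log ratio the call of Kng2 ended (-2.01, adjusted p = 0.132), as did that of Pank1 (-1.14, adjusted p = 0.0679). Pank1, which encodes a kinase of coenzyme A synthesis, fell by 1.08 ± 0.17 (adjusted p = 0.00825). The members that rose were Bmp8b, Adrb3, Fgf21 and Esrrg. Ppargc1a, a coactivator of mitochondrial genes, stood at -0.20 ± 0.16 (adjusted p = 0.432), the deiodinase gene Dio2 at -1.10 ± 0.47 (adjusted p = 0.148). The elongase gene Elovl3 stood at 0.85 ± 0.46 (adjusted p = 0.249) and the cytochrome oxidase gene Cox8b at -0.96 ± 0.34 (adjusted p = 0.0933). Without 11-month-old array 4 Dio2 and Cox8b passed (adjusted p = 0.0213 and 0.0193), and Cox8b passed without 11-month-old array 3 (adjusted p = 0.0424). Both passed with each age modelled alone (adjusted p = 0.0489 and 0.0333). The brown fat list passed without 6-week-old array 2 or 11-month-old array 3 or 4 (adjusted p = 0.0259, 0.0304 and 0.0225). It also passed with no filter on dim probes (adjusted p = 0.0409), the strict filter (0.0453) and each age modelled alone (0.0269). The call of Fgf21 ended without 6-week-old array 1, 3 or 4 or 11-month-old array 2 (adjusted p = 0.0513 to 0.101).

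White fat-selective genes rose in 10 of 24 measured members, 11 when adjusted over the list alone, with a median of 0.46 (camera adjusted p = 7.45e-07; adjusted p = 0.154 with an estimated correlation). Fabp5, a fatty acid carrier, rose by 2.31 ± 0.27 and the receptor gene Adgrg2 by 2.12 ± 0.14 (adjusted p = 0.00296 and 0.000593), while the leptin gene Lep stood at 0.90 ± 0.35 (adjusted p = 0.119). Of 23 general adipocyte genes 14 rose, with 17 higher and 1 lower when adjusted over the list alone and a median of 0.48 (camera adjusted p = 7.45e-07; adjusted p = 0.24 with an estimated correlation). Adrb1, a beta-adrenergic receptor gene, rose by 1.08 ± 0.17 (adjusted p = 0.00783), the lipase inhibitor gene G0s2 by 0.91 ± 0.17 (adjusted p = 0.0126). Cfd, the gene of adipsin, rose by 1.40 ± 0.30 (adjusted p = 0.0226) and the adiponectin gene Adipoq by 0.40 ± 0.08 (adjusted p = 0.0147). Without array 3 the calls of Cfd, G0s2 and Adipoq ended (adjusted p = 0.0874, 0.0558 and 0.0652), and those of Cfd and Adipoq ended also without array 2 or 4 and that of Cfd without array 1. For lipogenesis the camera adjusted p was 1.15e-11, and the adjusted p = 0.472 with an estimated correlation; 23 members rose when adjusted over the list alone. Among beige fat-associated genes 3 of 13 rose (Klhl13, Slc27a1 and Fgf21) and 2 fell (Kcnk3 and P2rx5), with the same counts adjusted over the list alone and camera adjusted p = 0.965. The list median was -0.10, its mean 0.10 and its test direction down. The calls of Klhl13 (without array 1 or 3), Kcnk3 (1, 3 or 4) and Fgf21 (1, 3 or 4) ended with adjusted p between 0.0525 and 0.101, and that of Fgf21 also without 11-month-old array 2 (adjusted p = 0.0513).

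The medians of the respiratory chain and the tricarboxylic acid cycle at 6 weeks lay nearer to 0 under median centring. In the nuclear-encoded respiratory chain 12 of 77 members fell and 2 rose (Atp5c1 and Atp5g3), or 27 and 2 when adjusted over the list alone. The list median was -0.27 (camera adjusted p = 2.97e-10; adjusted p = 0.952 with an estimated correlation), and under median centring it was -0.014 (adjusted p = 0.0682). The succinate dehydrogenase gene Sdhb fell by 0.64 ± 0.15 (adjusted p = 0.0277) and the cytochrome c1 gene Cyc1 by 0.56 ± 0.14 (adjusted p = 0.0314). Both calls ended without any 1 of the 4 arrays of this age (adjusted p = 0.0547 to 0.134), and that of Cyc1 without 11-month-old array 1 (adjusted p = 0.05). In the tricarboxylic acid cycle 4 of 23 members fell (Idh3b, Sdhb, Fh1 and Suclg2) and 2 rose, or 13 and 4 when adjusted over the list alone. The list median was -0.40 (camera adjusted p = 0.00949; adjusted p = 0.952 with an estimated correlation), and under median centring it was -0.13 (adjusted p = 0.178). The members that rose were the pyruvate carboxylase gene Pcx, by 1.15 ± 0.12 (adjusted p = 0.00179), and Pdhx. In fatty acid oxidation 4 of 30 members rose, Ehhadh, Acaa1b and Cpt1a among them, and 4 fell (Etfa, Etfb, Acads and Acadsb), or 4 and 7 when adjusted over the list alone (median -0.23, camera adjusted p = 0.277). Single arrays of the age ended the calls of Idh3b and Etfa (any of the 4), Ehhadh (1, 2 or 3), Acaa1b (2, 3 or 4) and Pdhx (1 or 2), with adjusted p between 0.05 and 0.168. Single 11-month-old arrays ended those of Idh3b (1 or 2), Etfa (1, 2 or 3) and Ehhadh (1), with adjusted p between 0.0545 and 0.0653. Skeletal muscle genes varied between the same arrays. Their list medians were -0.16, -2.77, 1.27 and -2.03 in 6-week-old arrays 1 to 4, the respiratory chain medians were -0.56, -0.15, -0.27 and -0.13, and the fatty acid oxidation medians -0.53, 0.07, -0.29 and -0.14.

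Of 44 skeletal muscle genes 0 passed the limma test at 6 weeks, over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05 (fry adjusted p = 0.566). The oxygen carrier gene Mb, at 1.73 ± 0.59 (adjusted p = 0.0839), passed without 11-month-old array 4 (adjusted p = 0.028). The list median of -0.77 gave a camera adjusted p of 0.0211, a call that ended with an estimated correlation (adjusted p = 0.952). It ended also without array 2 (median -0.08, adjusted p = 0.827) or array 4 (median -0.28, adjusted p = 0.491).

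Genes of other cell types changed in small numbers at 6 weeks. Interferon-stimulated genes rose in 3 of 37 members (Lgals3bp, Ifit3 and Irf7; 1 adjusted over the list alone; median 0.05, camera adjusted p = 0.758). In the macrophage and myeloid list Cd14, an endotoxin co-receptor gene, rose by 0.90 ± 0.14 (adjusted p = 0.00779) and the lysozyme gene Lyz2 fell. The other 27 of 29 members were not past the test (1 rose adjusted over the list alone; median 0.02, camera adjusted p = 0.938). In the fibroblast and extracellular matrix list 3 of 32 members rose, the collagen genes Col5a1 (0.87 ± 0.07, adjusted p = 0.00107) and Col5a2 and the matrix gene Sparc (3 adjusted over the list alone; median 0.11, camera adjusted p = 0.176). In the endothelial list 3 of 16 members fell (Tie1, Flt1 and Pecam1; 4 adjusted over the list alone; median -0.12, camera adjusted p = 0.0548). The endothelial list passed without 11-month-old array 1, 3 or 4 (adjusted p = 0.0486, 0.0304 and 0.0225) and the matrix list without 11-month-old array 3 (adjusted p = 0.038) or under median centring (median 0.30, adjusted p = 0.0147). The endothelial list also passed with no filter on dim probes, the mean of all probes, no dye coefficient, a dye coefficient per age and each age modelled alone (adjusted p = 0.0127 to 0.0435). Of 21 lymphocyte genes 0 passed the limma test, adjusted over all genes or over the list alone, and 3 had an unadjusted p under 0.05 (median -0.09, camera adjusted p = 0.148, fry adjusted p = 0.24). In the smooth muscle and pericyte list 1 of 12 members rose, the actin gene Actg2 (1.13 ± 0.11, adjusted p = 0.00168), and 2 fell (Rgs5 and Smtn). The counts were 3 and 2 adjusted over the list alone (median 0.09, camera adjusted p = 0.758). Single arrays of the age ended the calls of Ifit3, Lyz2 and Flt1 (any of the 4), Irf7 (2, 3 or 4), Tie1 (1, 2 or 3) and Sparc (3), with adjusted p between 0.0563 and 0.15. Single 11-month-old arrays ended those of Ifit3 (2), Irf7 (1 or 3), Lyz2 (1 or 2) and Flt1 (1, 2 or 4), with adjusted p between 0.0518 and 0.0674.

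The count of 3520 moved with every 6-week-old array left out, where fewer arrays remain to make calls. It was 1238, 1573, 1544 and 2067 without arrays 1 to 4. It was 801 without the 3 arrays whose skeletal muscle medians were largest in size (6-week-old arrays 2 and 4 at -2.77 and -2.03 and 11-month-old array 4 at 1.57, chosen after seeing the data), a model that kept 6-week-old array 3 at 1.27, and 2278 with the log ratios of the scanner software. Camera with a preset correlation of 0.01 called 6 of the 25 lists at 6 weeks, 0 with an estimated correlation, and fry called 3 for movement in one direction.

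**Figure D1:**
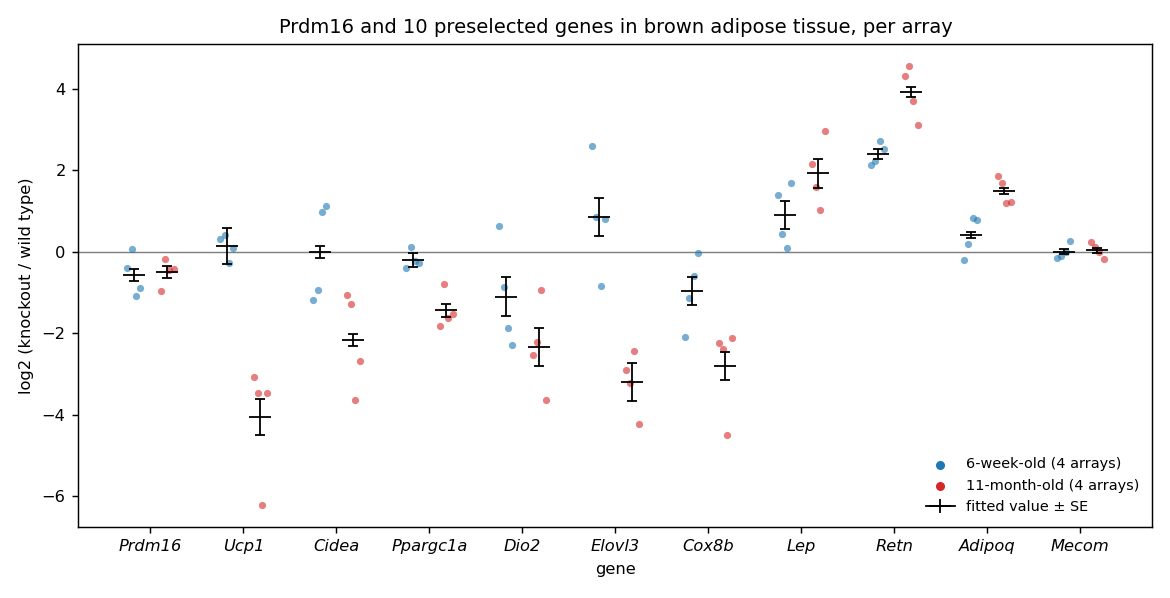
Log2 ratio of knockout over wild type for selected genes in each array, with 6-week-old and 11-month-old mice side by side; points are single arrays and the black marks are the fitted value ± SE of the limma model (n = 4 arrays per age). The points are not adjusted for dye, which splits Cidea into pairs of arrays; Ucp1 stands at a fitted 0.13 at 6 weeks and -4.05 at 11 months, and Retn at 2.40 and 3.92.

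The second comparison asked the same of 11-month-old mice. Brown fat genes fell in knockout tissue, led by Ucp1 at -4.05 ± 0.44 (16.6-fold lower, adjusted p = 0.000419), and Cidea fell by 2.16 ± 0.14 (4.48-fold lower, adjusted p = 5.17e-05). Of 39 measured brown fat-selective genes 30 fell, and of 77 nuclear-encoded respiratory chain genes 73 fell, with a median of -1.26. Both list calls ended with an estimated correlation (adjusted p = 0.173 and 0.224). By fry, which does not compare a list with other genes, the adjusted p was 0.000304 and 0.000493. Of 24 white fat-selective genes 16 rose and 8 were not past the test, and of 23 general adipocyte genes 14 rose, 3 fell and 6 were not past it. These list calls ended with an estimated correlation as well (adjusted p = 0.0778 and 0.217), and fry gave adjusted p = 1.75e-05 and 0.000304. The largest increases in these lists were in Cfd, the gene of the serine protease adipsin, at 4.54 ± 0.30 (23.3-fold, adjusted p = 6.11e-05), and Retn at 3.92 ± 0.12 (15.2-fold, adjusted p = 8.03e-06). Interferon-stimulated genes rose in 30 of 37 measured members, macrophage and myeloid genes in 20 of 29, and fibroblast and matrix genes in 21 of 32. These list calls also ended with an estimated correlation (adjusted p = 0.115, 0.115 and 0.224), and fry gave adjusted p = 0.000122, 0.000457 and 0.00135.

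In all, 7544 genes (34.7%) changed at 11 months, 3897 higher and 3647 lower, and 571 of the higher and 573 of the lower genes changed by at least 2-fold. Under median centring the split was 3482 higher and 1432 lower, or 70.9% higher in place of 51.7%, and the median of all genes moved to 0.09. With the scanner software's log ratio the balance turned the other way, with 4355 higher and 5228 lower (45.4% higher). After Cfd, the largest increases with one sign in all 4 arrays were in the sulfotransferase gene Chst1 (4.49 ± 0.08, adjusted p = 5.68e-07), the glutathione transferase gene Gsta3 (4.36 ± 0.29), Ifi27l2a (4.23 ± 0.23) and the cytochrome P450 gene Cyp2e1 (4.11). They were followed by Retn, Psat1, an enzyme gene of serine synthesis (3.91 ± 0.15), the transporter gene Slc6a13 (3.90), the transferrin gene Trf (3.79) and the complement factor B gene Cfb (3.51). After Ucp1, the largest decreases were in Kng2 (-3.93 ± 0.11) and Kng1 (-3.90 ± 0.19), whose probes may read both transcripts, the acyl-CoA thioesterase gene Acot11 (-3.79 ± 0.40) and Aspg (-3.73). Next came the fatty acid carrier gene Fabp3 (-3.37), the cytochrome oxidase gene Cox7a1 (-3.29 ± 0.40, 9.76-fold lower, adjusted p = 0.000708), Elovl3 (-3.19 ± 0.46), the malic enzyme gene Me3 (-3.16) and Kcp (-3.09).

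The brown fat-selective list had 30 of 39 members lower, 2 higher (Adrb3 and Gatm) and 7 not past the test, with the same counts adjusted over the list alone. The list median was -1.48 (camera adjusted p = 4.26e-12; adjusted p = 0.173 with an estimated correlation). Dio2 fell by 2.33 ± 0.47 (adjusted p = 0.00676), Ppargc1a by 1.44 ± 0.16 (adjusted p = 0.000478) and Cox8b by 2.81 ± 0.34 (adjusted p = 0.000664). Fatty acid oxidation genes fell in 22 of 30 members and rose in 2, Cpt1a among them, or 24 and 3 when adjusted over the list alone. The list median was -1.32 (camera adjusted p = 3.76e-08; adjusted p = 0.394 with an estimated correlation). Cpt1b, a carnitine acyltransferase gene needed for fatty acid entry into mitochondria, fell by 2.74 ± 0.35 (6.68-fold lower, adjusted p = 0.000888). Acaa2, a thiolase gene of the last step of beta-oxidation, fell by 2.50 ± 0.32 (adjusted p = 0.000823). In the tricarboxylic acid cycle 20 of 23 members fell, 21 adjusted over the list alone, and Pcx rose (median -1.30, camera adjusted p = 4.26e-11; adjusted p = 0.179 with an estimated correlation). The succinyl-CoA ligase genes Sucla2 and Suclg1 fell by 2.48 ± 0.25 (adjusted p = 0.000297) and 2.18 ± 0.24 (adjusted p = 0.000465). The respiratory chain list held 73 members lower, 1 higher (Atp5g3) and 3 not past the test, or 73 and 2 adjusted over the list alone (camera adjusted p = 1.43e-32; adjusted p = 0.224 with an estimated correlation). Sdhd fell by 1.78 ± 0.13 (adjusted p = 7.29e-05). Skeletal muscle list medians were -0.29, -0.90, -0.42 and 1.57 in 11-month-old arrays 1 to 4, beside respiratory chain medians of -1.25, -1.38, -1.45 and -0.90.

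White fat-selective genes rose in 16 of 24 members, 17 adjusted over the list alone, with a median of 1.24 (camera adjusted p = 2.54e-09; adjusted p = 0.0778 with an estimated correlation). The amino acid transporter gene Slc7a10 rose by 3.12 ± 0.09 (8.70-fold, adjusted p = 6.3e-06), the methyltransferase gene Nnmt by 2.92 ± 0.16 (adjusted p = 2.73e-05) and Lep by 1.93 ± 0.35 (adjusted p = 0.00441). Of 23 general adipocyte genes 14 rose and 3 fell (Adrb1, Cebpb and G0s2), with the same counts adjusted over the list alone and a median of 0.60 (camera adjusted p = 0.00091; adjusted p = 0.217 with an estimated correlation). The lipid droplet genes Plin4 and Cidec rose by 2.30 ± 0.16 (adjusted p = 6.99e-05) and 1.84 ± 0.12 (adjusted p = 5.17e-05) and Adipoq by 1.49 ± 0.08 (adjusted p = 2.28e-05). Lipogenesis genes went both ways, with 5 of 26 higher (Me1, Fads1, Dgat2, Srebf1 and Dgat1) and 4 lower (Gpd1, Elovl6, Acacb and Mlxipl), the same adjusted over the list alone (median 0.21, camera adjusted p = 0.503, and 0.00772 without array 4). Among 13 beige fat-associated genes 2 rose (Klhl13 and Slc27a1) and 3 fell (Kcnk3, Slc36a2 and P2rx5), the same adjusted over the list alone; the median was 0.04, the mean -0.03 and the test direction down (camera adjusted p = 0.834).

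Interferon-stimulated genes rose in 30 of 37 members and fell in 1 (Ifi27), or 31 and 1 adjusted over the list alone, with a median of 0.83 (camera adjusted p = 3.39e-12; adjusted p = 0.115 with an estimated correlation). Lgals3bp rose by 2.25 ± 0.13 (adjusted p = 3.4e-05), Rtp4 by 1.87 ± 0.21 (adjusted p = 0.000522) and Ifit3, an antiviral effector gene, by 1.69 ± 0.07 (3.22-fold, adjusted p = 1.18e-05). Another kept probe of Lgals3bp rose by less, at 0.92 (adjusted p = 0.000643 in a limma model of all kept probes). Macrophage and myeloid genes rose in 20 of 29 members, 23 adjusted over the list alone, with a median of 0.62 (camera adjusted p = 1.7e-07; adjusted p = 0.115 with an estimated correlation). The chemokine gene Ccl2 rose by 1.80 ± 0.26 (adjusted p = 0.0015) and the galectin gene Lgals3 by 1.63 ± 0.26 (adjusted p = 0.0025). Fibroblast and extracellular matrix genes rose in 21 of 32 members, with 22 higher and 1 lower adjusted over the list alone and a median of 0.70 (camera adjusted p = 3.1e-07; adjusted p = 0.224 with an estimated correlation). The thrombospondin gene Thbs1 rose by 2.29 ± 0.24 (adjusted p = 0.00034) and the fibrillar collagen genes Col5a1 and Col3a1 by 1.73 ± 0.07 (adjusted p = 1.42e-05) and 1.90 ± 0.35 (adjusted p = 0.00451). Smooth muscle and pericyte genes rose in 7 of 12 members, with 9 higher and 1 lower adjusted over the list alone (median 0.38, camera adjusted p = 0.0098; adjusted p = 0.173 with an estimated correlation). The actin gene Acta2 rose by 0.70 ± 0.10 (adjusted p = 0.00176). In the endothelial list 3 of 16 members rose (Plvap, Robo4 and Vwf), the same adjusted over the list alone (median 0.12, camera adjusted p = 0.387). Among 21 lymphocyte genes 2 rose (Coro1a and Cd52) and 1 fell (Ccr7), the same adjusted over the list alone; the median was -0.0031, the mean 0.03 and the test direction down (camera adjusted p = 0.862). Without single 11-month-old arrays the calls of Robo4 (2, 3 or 4) and Ccr7 (1, 2 or 4) ended (adjusted p = 0.0561 to 0.0879). Of 44 skeletal muscle genes Tpm3 rose and 43 did not pass, over all genes or adjusted over the list alone (median 0.0040, camera adjusted p = 0.834).

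The count of 7544 was 5027 without 11-month-old array 2 and 4871 without the 3 arrays of largest skeletal muscle median in size. Camera called 12 of the 25 lists, 0 with an estimated correlation, and fry called 15 for movement in one direction.

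**Figure D2:**
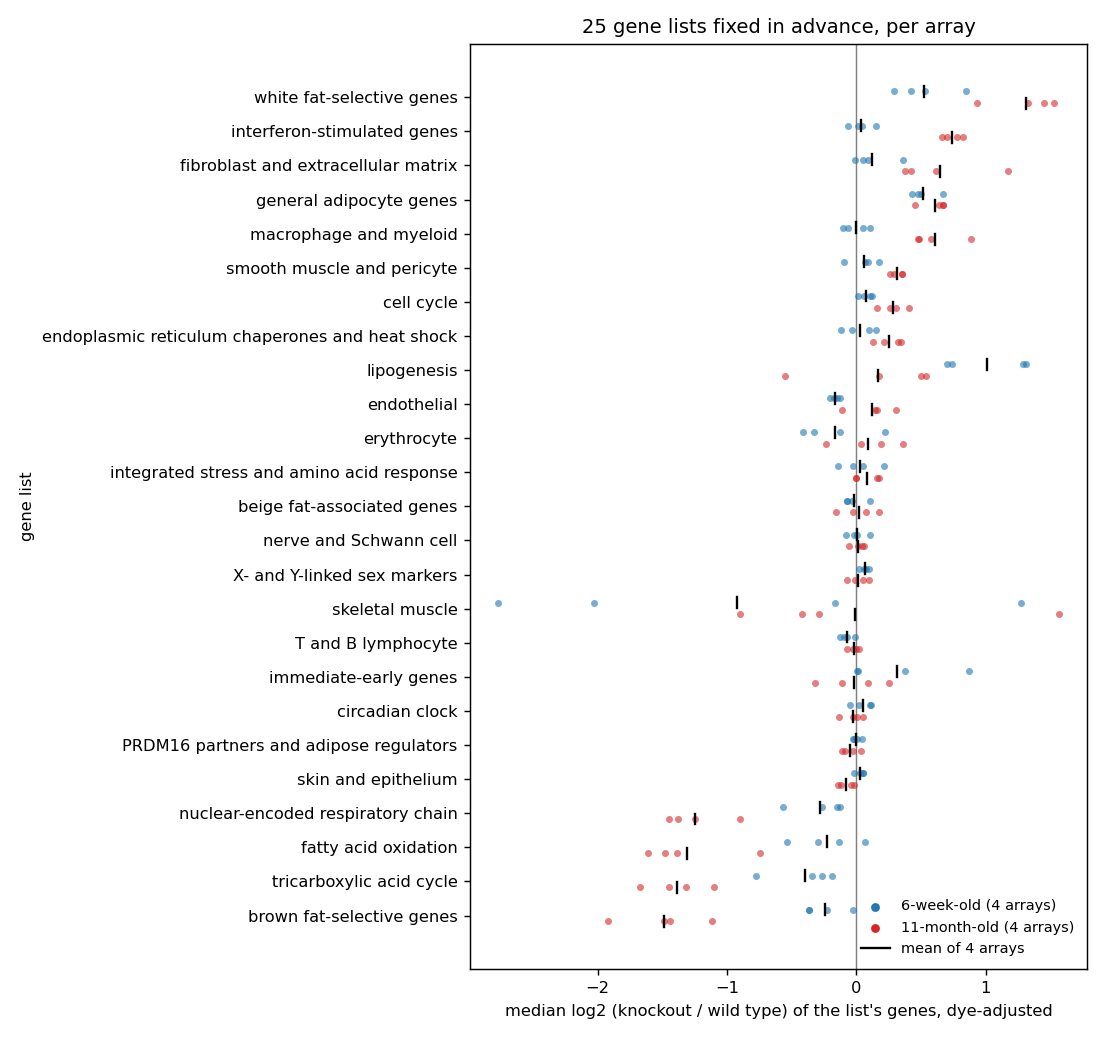
Median log2 ratio of knockout over wild type of gene lists in each array after removal of the dye term, with the ages side by side; points are arrays and the bars their mean (n = 4 arrays per age). Brown fat-selective medians lie between -0.37 and -0.023 at 6 weeks and between -1.92 and -1.12 at 11 months, while skeletal muscle medians run from -2.77 to 1.27 and from -0.90 to 1.57.

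The third comparison tested whether the effect of the knockout differed between the ages, as the 11-month-old minus the 6-week-old log2 ratio. Thermogenic and oxidative genes separated the ages, with Ucp1 at -4.18 ± 0.63 (adjusted p = 0.00544), Elovl3 at -4.04 ± 0.66 (adjusted p = 0.00709) and Acot11 at -4.83 ± 0.57 (adjusted p = 0.00274). The difference was negative and past the test in 24 of 39 brown fat-selective genes and 69 of 77 respiratory chain genes. It was positive and past the test in 22 of 37 interferon-stimulated genes, led by Ifi27l2a at 4.76 ± 0.32 (adjusted p = 0.000802). The calls of these 3 lists ended with an estimated correlation (adjusted p = 0.269, 0.308 and 0.188), and fry gave adjusted p = 0.00408, 0.00778 and 0.00408. The ages were processed as separate batches per the labels, and per the file headers each age lay on a slide of its own, so age and batch cannot be told apart.

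The difference passed in 3952 genes (18.2%), positive in 1840 and negative in 2112, and reached at least 2-fold in 349 and 464 of these. Under median centring it passed in 548 genes, 328 positive and 220 negative, or 59.9% positive in place of 46.6%. With the scanner software's log ratio it was positive in 2047 and negative in 2801 (42.2% positive). Among genes whose arrays did not overlap between the ages, the positive differences were largest in Ifi27l2a, Cyp2f2 (4.30 ± 0.54), Gsta3 (3.80 ± 0.42), the serine synthesis gene Phgdh (3.36 ± 0.26, adjusted p = 0.000844), and Chst1 (3.29 ± 0.11). They were followed by Cfd (3.14 ± 0.43), Cdsn (2.77), the chemerin gene Rarres2 (2.73), Thbs1 (2.55) and Slc6a13 (2.52). The most negative, after Acot11, Ucp1 and Elovl3, were in Aspg (-3.77 ± 0.35), the acyl-CoA synthetase gene Acsl5 (-3.68 ± 0.49), Slc2a5 (-3.44 ± 0.88), Rab6b (-3.01), Sorcs2 (-2.94), Bmp8b (-2.92) and Adprhl1 (-2.79). The call of Slc2a5 (adjusted p = 0.0343) ended without 6-week-old array 1 or 2 or 11-month-old array 2 or 3 (adjusted p = 0.0607 to 0.0976), under median centring (0.113) and with no dye coefficient (0.0765), and that of Slc6a13 under median centring (0.0728).

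By list, the brown fat-selective difference had a median of -1.23, with 27 members negative and 1 positive adjusted over the list alone (camera adjusted p = 2.4e-11; adjusted p = 0.269 with an estimated correlation). Fatty acid oxidation was negative in 16 of 30 members and positive in Cpt1a, or 21 and 1 adjusted over the list alone (median -0.84, camera adjusted p = 6.81e-08; adjusted p = 0.404 with an estimated correlation). The tricarboxylic acid cycle was negative in 20 of 23 and positive in Pcx, the same adjusted over the list alone (median -1.18, camera adjusted p = 3.21e-09; adjusted p = 0.281 with an estimated correlation). The respiratory chain was positive in Atp5g3, and 72 members were negative and 2 positive adjusted over the list alone (median -0.92, camera adjusted p = 5.24e-29; adjusted p = 0.308 with an estimated correlation). In lipogenesis Elovl6 differed by -2.68 ± 0.41 (adjusted p = 0.00588) and Scd1 by -2.45 ± 0.42 (adjusted p = 0.00879, and 0.0784 under median centring). The list was negative in 9 of 26 members and positive in 2 (Fads1 and Dgat2), or 15 and 2 adjusted over the list alone (median -1.04, camera adjusted p = 0.000143; adjusted p = 0.429 with an estimated correlation). White fat-selective genes were positive in 6 of 24, the same adjusted over the list alone (median 0.48, camera adjusted p = 0.00299; adjusted p = 0.269 with an estimated correlation). Psat1 differed by 1.86 ± 0.22 (adjusted p = 0.00265) and Slc7a10 by 1.72 ± 0.12 (adjusted p = 0.000802). General adipocyte genes were positive in 5 of 23 (Cfd, Plin4, Cidec, Cebpa and Adipoq) and negative in 4 (Adrb1, G0s2, Cebpb and Slc2a4), or 8 and 6 adjusted over the list alone. The list had a median of -0.06, a mean of 0.19 and a test direction of up (camera adjusted p = 0.493). The call of Cebpb ended without 11-month-old array 1 (adjusted p = 0.0517) and under median centring (0.152), and that of Cidec under median centring (0.0594) and with no dye coefficient (0.145). Beige fat-associated genes were negative in 3 of 13 (Slc36a2, Kcnk3 and P2rx5), the same adjusted over the list alone, with a median of 0.07, a mean of -0.13 and a test direction of down (camera adjusted p = 0.676).

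The interferon-stimulated list had 27 members positive adjusted over the list alone and a median of 0.73 (camera adjusted p = 2.14e-12; adjusted p = 0.188 with an estimated correlation), with Ifit3 at 1.40 ± 0.10 (adjusted p = 0.000802). Macrophage and myeloid genes were positive in 7 of 29 members, 17 adjusted over the list alone (median 0.61, camera adjusted p = 4.04e-07; adjusted p = 0.188 with an estimated correlation), with Ccl2 at 2.26 ± 0.37 (adjusted p = 0.00709). Fibroblast and matrix genes were positive in 12 of 32, 15 adjusted over the list alone (median 0.43, camera adjusted p = 9.44e-06; adjusted p = 0.308 with an estimated correlation). Endothelial genes were positive in 2 of 16 (Robo4 and Plvap), 6 adjusted over the list alone (median 0.35, camera adjusted p = 0.00503; adjusted p = 0.308 with an estimated correlation). Lymphocyte genes were positive in 3 of 21, Coro1a and Ltb among them, 2 adjusted over the list alone, with a median of -0.01, a mean of 0.11 and a test direction of up (camera adjusted p = 0.397). Smooth muscle and pericyte genes were positive in 3 of 12 (Smtn, Acta2 and Notch3) and negative in Actg2, or 5 and 1 adjusted over the list alone (median 0.24, camera adjusted p = 0.0839, and 0.0379 without 6-week-old array 3). That list passed as well with no background subtraction, the scanner software's log ratio, the deposited log2 ratios and no filter on dim probes (adjusted p = 0.0424 to 0.0457). The skeletal muscle list had 1 of 44 members past the test (Tpm3), the same adjusted over the list alone, and a median of 0.77 (camera adjusted p = 0.0456; adjusted p = 0.796 with an estimated correlation). That call ended without 6-week-old array 2 (median 0.08, adjusted p = 0.722), 6-week-old array 4 (adjusted p = 0.361) or 11-month-old array 4 (adjusted p = 0.65). It also ended with no background subtraction (adjusted p = 0.078), the scanner software's log ratio (0.0503), the deposited log2 ratios (0.0746), the strict filter on dim probes (0.0738) and the mean of all probes (0.0579).

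The count of 3952 was 2218 without 6-week-old array 2, 2481 without 6-week-old array 4, 2118 without 11-month-old array 2 and 689 without the 3 arrays of largest skeletal muscle median in size. Without a dye coefficient it was 2518. Camera called 12 of the 25 lists, 0 with an estimated correlation, and fry called 12 for movement in one direction.

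Across the 21742 genes the knockout effects at the 2 ages correlated at Pearson r = 0.436 and Spearman rho = 0.336, and genes are not independent replicates. Of the genes higher at 6 weeks 47.3% were also higher at 11 months, 944 genes against 357.6 for independent lists of the same sizes. Another 749 genes were lower at both ages, against 255.8. The genes higher at 6 weeks and lower at 11 months numbered 150, against 334.6, and 88 went the other way, against 273.3. The white fat gene Retn, the kininogen genes Kng1 and Kng2 and the clock gene Hlf were among those called in one direction at both ages. Adrb1 was higher at 6 weeks and lower at 11 months (difference -1.96 ± 0.24, adjusted p = 0.00296). The call of Hlf at 11 months ended without 11-month-old array 1, 2 or 3 (adjusted p = 0.0587 to 0.0821).

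**Figure D3:**
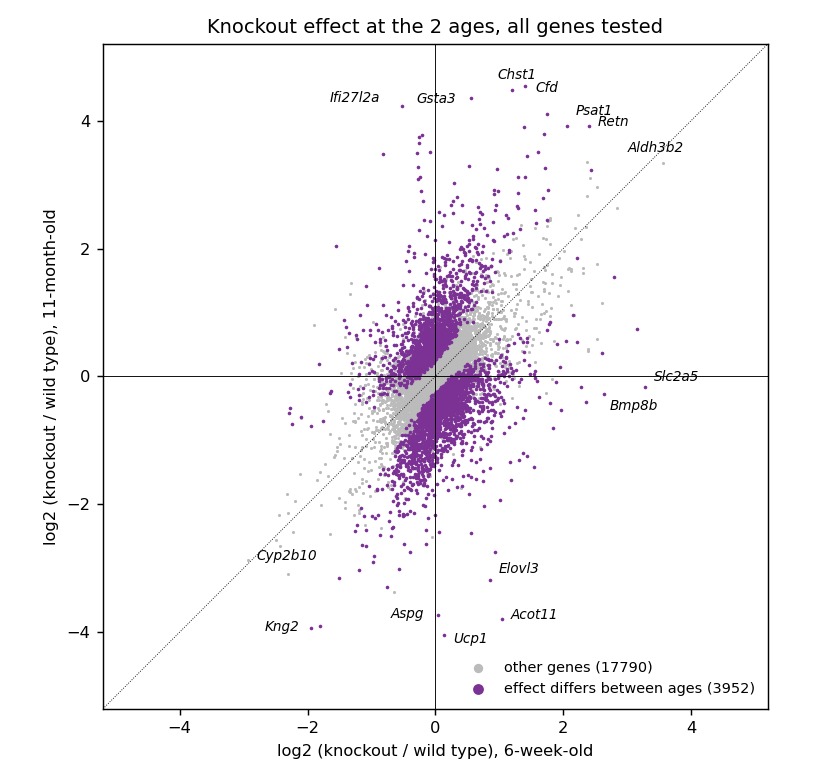
Log2 ratio of knockout over wild type at 6 weeks (x axis) against 11 months (y axis) for the 21742 genes tested; each point is a gene, the dotted line marks equal effects, and coloured points are the 3952 genes whose effect differed between the ages. Aldh3b2, Retn and Psat1 lie high at both ages, while Ucp1, Acot11 and Elovl3 lie low at 11 months alone.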

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

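All tests of explanations in this part were chosen after the result they address was seen. Values of single arrays were adjusted for dye. Among 225 groups of 4 arrays, 1 per gene or list and age, 16 had an array far from the other 3, where chance picks out about 1 in 20 groups, or 11.2. In the 6-week-old mice these were Gldn in array 1 (-0.607, against -3.30 to -2.90 in the others), Sgk2 in array 1 (-3.25, against -2.05 to -1.86), and Mosc1 in array 1 (3.88, against 2.43 to 2.55). Others at that age were Cfd in array 3 (2.07, against 1.12 to 1.23), Ndufs7 in array 1 (-1.24, against -0.564 to -0.442), Slc27a1 in array 2 (1.19, against 1.06 to 1.07) and Ppargc1a in array 2 (0.151, against -0.359 to -0.273). In the 11-month-old mice they were Prdm16 in array 2 (0.0574, against -0.722 to -0.663), Col1a1 in array 3 (3.22, against 1.02 to 1.33) and the general adipocyte list in array 3 (0.457, against 0.639 to 0.671). Array 4 of that age stood apart in 6 genes: Elovl3 (-4.59, against -2.85 to -2.53), Gsta3 (3.13, against 4.63 to 4.94), Plin4 (2.78, against 2.07 to 2.19), Ndufa1 (-1.22, against -1.96 to -1.86), Me1 (0.316, against 2.54 to 2.97) and Elovl6 (-2.36, against -0.91 to -0.826).

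The knockout effect differed between the ages, by a limma test of the difference itself, in 59 of 71 genes examined. Many of the 71 were named because they passed this same test, so that share says nothing about genes at large, of which 18.2% passed. The 11-month-old ratio was the lower in Acot11 (-4.83), Ucp1 (-4.18), Elovl3 (-4.04), Aspg (-3.77), Acsl5 (-3.68), Slc2a5 (-3.44), Rab6b (-3.01), Sorcs2 (-2.94), Bmp8b (-2.92), Adprhl1 (-2.79), Elovl6 (-2.68), Cox7a1 (-2.53), Pdk4 (-2.50), Scd1 (-2.45), Cpt1b (-2.34), Cidea (-2.16), Kng1 (-2.10), Kng2 (-1.99), Adrb1 (-1.96), and Gpd1 (-1.86). It was lower by less in Cox8b (-1.85), Suclg1 (-1.68), Sucla2 (-1.62), Bhlhe40 (-1.62), Acacb (-1.53), Nfil3 (-1.45), Ppargc1a (-1.24), Cebpb (-1.13), Kcnk3 (-0.947), Ppargc1b (-0.93), Esrra (-0.776) and Eif2s3y (-0.732). It was the higher in Tyrobp (0.766), Adgre1 (0.77), Col5a1 (0.866), Lgals3bp (1.03), Hlf (1.05), Adipoq (1.09), Ifit3 (1.40), Psmb9 (1.49), Retn (1.52), Rtp4 (1.54), Cidec (1.63), Plin4 (1.66), Slc7a10 (1.72) and Col3a1 (1.72). It was higher by more in Dbp (1.84), Psat1 (1.86), Ccl2 (2.26), Slc6a13 (2.52), Thbs1 (2.55), Rarres2 (2.73), Cdsn (2.77), Cfd (3.14), Chst1 (3.29), Phgdh (3.36), Gsta3 (3.80), Cyp2f2 (4.30) and Ifi27l2a (4.76). Leaving out single arrays ended the calls of Slc2a5 (6-week-old array 1 or 2, 11-month-old array 2 or 3), Cox7a1 (6-week-old 2, 3 or 4, 11-month-old 1 or 2), Pdk4 (the same arrays), Cpt1b and Suclg1 (6-week-old 2, 11-month-old 2), with adjusted p between 0.0503 and 0.0976. They also ended those of Cox8b and Sucla2 (6-week-old 2, 3 or 4, 11-month-old 1, 2 or 3), Cebpb (11-month-old 1), Ppargc1b (6-week-old 2 or 4, 11-month-old 1, 2 or 3), Hlf (6-week-old 1, 2 or 3, 11-month-old 1 or 2) and Col3a1 (any 6-week-old, 11-month-old 1 or 2), with adjusted p between 0.0512 and 0.112. Median centring ended 19 of the 59 calls, with adjusted p between 0.0509 and 0.152: those of Slc2a5, Cox7a1, Pdk4, Scd1, Cpt1b, Gpd1, Cox8b, Suclg1, Acacb, Cebpb, Ppargc1b, Esrra, Eif2s3y, Hlf, Psmb9, Retn, Cidec, Dbp and Slc6a13. No dye coefficient ended those of Slc2a5, Cox8b, Tyrobp, Hlf, Cidec, Col3a1 and Dbp (adjusted p = 0.0511 to 0.145), and no filter on dim probes that of Col3a1 (adjusted p = 0.0624).

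Of the 25 lists, 12 passed the camera test of the difference with the preset correlation and 0 with an estimated one. The 12 had medians of -1.23 (brown fat-selective), -1.18 (tricarboxylic acid cycle), -1.04 (lipogenesis), -0.918 (respiratory chain), -0.845 (fatty acid oxidation), 0.24 (cell cycle), 0.345 (endothelial), 0.432 (fibroblast and matrix), 0.481 (white fat-selective), 0.612 (macrophage and myeloid), 0.733 (interferon-stimulated) and 0.768 (skeletal muscle). The skeletal muscle call ended without 6-week-old array 2 or 4 or 11-month-old array 4 (adjusted p = 0.722, 0.361 and 0.65), and under 5 of the other settings (adjusted p = 0.0503 to 0.078). Age and batch cannot be told apart in any of these differences.

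Skeletal muscle genes differed between arrays of the same comparison, with list medians from -2.77 to 1.27 at 6 weeks and from -0.90 to 1.57 at 11 months. A uniform effect of the knockout is argued against by the range of 4.04 between the 6-week-old arrays, and dye bias by a difference of 3.30 between arrays of one age and one dye orientation. In the arrays with a median beyond 1 in size, at least 90.9% of the 44 members moved with the median. Of the 4 brightest members, Tnnc2 ran from -3.38 to 3.40 and Myh4 from -4.10 to 4.35 at 6 weeks. Myl1 ran from -0.841 to 0.47, which unequal muscle would have to explain. Tpm3 ran from -0.138 to 0.139 at 6 weeks. At 11 months Tpm3 stood at 0.413, 0.603, 0.873 and 0.643 in arrays 1 to 4, beside list medians of -0.29, -0.90, -0.42 and 1.57. Tpm3 thus did not follow the list at either age, and its small range does not count against unequal muscle. Unequal amounts of skeletal muscle in the dissected samples stay open as a source, and may add to the spread of genes that muscle expresses.

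Brown fat and mitochondrial genes were lower at 11 months. The general adipocyte list was not lower, with a lowest array median of 0.457. Its genes can change within each cell, so the list does not count adipocytes, and a lower share of them stays open. Under 4 other treatments of the signal the brown fat median came no nearer to 0 than -1.30. Among them, median centring and the scanner software's log ratio did not use the loess, which argues against the loess as the source. No background subtraction kept the loess, and the normalization of the deposited log2 ratios is not given. A bias that all these treatments share stays open. White fat carried over with the knockout samples stays open: of 3 brown fat identity genes chosen after their values were seen, Zic1 stood at 0.014 (95% interval -0.247 to 0.275), Lhx8 at 0.36 (-0.0708 to 0.792) and Ebf2 at -0.43 (-0.861 to -0.00258, adjusted p = 0.11), with all 3 intervals above the brown fat median of -1.48. They count against carry-over only if white fat lacks these transcripts, and that was not measured here. A change of the brown adipocytes themselves stays open as well and was not tested.

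Interferon-stimulated and macrophage genes were higher at 11 months. An equal rise of every other cell type, from a lower share of adipocytes, would raise the lymphocyte list as much as the macrophage list. It lay below the macrophage list by at least 0.482 in each of the 4 arrays. The matrix and smooth muscle lists rose (medians 0.70 and 0.38), and the endothelial list was not past camera (median 0.12). A lower share of adipocytes, with equal or unequal changes of the other cell types, stays open. Whether more macrophages could carry the interferon-stimulated genes stays open, since the interferon median exceeded the macrophage median by 0.0883, 0.344, -0.108 and 0.211 in arrays 1 to 4 (mean 0.134, SD 0.192). An interferon response in the tissue stays open too and was not tested.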

How the results depend on the processing

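The skeletal muscle covariate and the model without the 3 arrays of largest skeletal muscle median in size were chosen after seeing the data, and the other settings before. The covariate, the model without the 3 arrays, the intensity trend and the fold change were run for the counts of genes alone, and the replicate block for the difference alone. Under the settings run for them, no called gene or list changed direction, and 145 of 224 gene results and 60 of 75 list results kept their side of the threshold. The balance of calls did turn over: at 11 months 51.7% of genes were higher, against 45.4% with the scanner software's log ratio and 49.9% with the fold change, and 46.6% of the differences were positive, against 59.9% with median centring.

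Apart from single arrays left out, and besides Prdm16, median centring ended the most gene calls (49). At 6 weeks these were Olig1, Rbp4, Ndufs7, Sdhb, Cyc1, Pdhx, Idh3b, Ehhadh, Etfa, Ifit3, Irf7, Lyz2, Tie1, Flt1, Ppargc1b, Fgf21, Kcnk3, Dbp, Tef, Atf4, Prx, Ncmap, Adipoq, Dnajb9 and Ier3 (adjusted p = 0.0501 to 0.76), at 11 months Elovl6, Hspe1, Hlf, Th and Eif2s3y (0.0563 to 0.2), and 19 were differences between ages. No dye coefficient ended 18, at 6 weeks Adipoq, Cfd, Etfa, Flt1, Irf7, Lyz2, Rbp4, Sdhb and Sparc (0.0524 to 0.247), at 11 months Cd52 and Trib3 (0.0617 and 0.0525), and 7 differences. The other settings ended calls at 6 weeks, apart from the difference of Col3a1. The scanner software's log ratio ended 15, Cth, Cyc1, Ehhadh, Etfa, Flt1, Idh3b, Ier3, Ifit3, Irf7, Kng2, Lyz2, Pank1, Ppargc1b, Prx and Sdhb (0.0526 to 0.243). No background subtraction ended 9, Cth, Cyc1, Etfa, Flt1, Idh3b, Ifit3, Irf7, Lyz2 and Ppargc1b (0.0503 to 0.346), and the deposited log2 ratios ended 8 of these, that of Etfa excepted (0.0511 to 0.321). Each age alone ended 6, Dnajb9, Fgf21, Ier3, Kcnk3, Ncmap and Prx (0.0522 to 0.0942), and no filter on dim probes 4, Etfa, Flt1, Olig1 and Col3a1 (0.0508 to 0.0624).

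The genes changed at 6 weeks (3520) numbered 2278 with the scanner software's log ratio, 948 with median centring, 394 with a fold change of at least 2, 801 without the 3 arrays (660 of them shared with the 3520), and 1238 to 4278 with single arrays left out. Those at 11 months (7544) numbered 4914 with median centring, 1144 with the fold change, 4871 without the 3 arrays (4582 shared) and 5027 to 7643 with single arrays left out. The genes whose effect differed between the ages (3952) numbered 548 with median centring, 2518 with no dye coefficient, 813 with the fold change, 689 without the 3 arrays (665 shared) and 2118 to 3225 with single arrays left out. The fold change lowers a count by construction. With arrays left out fewer remain to make calls, so a lower count or an ended call need not point to the array left out. For the other settings the cause was not tested. Every other setting left these counts within 1.5 times.

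Prdm16 at 6 weeks (-0.58) was no longer past the threshold with no background subtraction (-0.60, adjusted p = 0.0622), the scanner software's log ratio (-0.64, 0.0757), median centring (-0.42, 0.238), the deposited log2 ratios (-0.60, 0.0612), no filter on dim probes (-0.58, 0.0512) or no dye coefficient (-0.58, 0.0843), and ran from -0.73 to -0.46 with single arrays left out. Prdm16 at 11 months (-0.50) was no longer past it with median centring (-0.27, 0.35) or no dye coefficient (-0.50, 0.077), and ran from -0.73 to -0.42 (-0.415) with single arrays left out. With no filter on dim probes the value did not move and more genes were tested; for the other settings the cause was not tested.

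The correlation between the ages (0.436) lay between 0.41 and 0.446 under other treatments and between 0.385 and 0.488 with single arrays left out (jackknife SE 0.0997). The lists past camera numbered 4 to 9 at 6 weeks, 11 to 13 at 11 months and 11 to 15 for the difference. At 6 weeks the call of the tricarboxylic acid cycle ended with the scanner software's log ratio (adjusted p = 0.0551) and median centring (0.178), that of the respiratory chain with median centring (0.0682) and that of skeletal muscle with the scanner software's log ratio (0.0551). The muscle covariate gave 2941, 7093 and 3409 genes, and an intensity trend 3645, 7765 and 4086.

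Replicate number as a block, which applies to the difference only, gave 4245 genes (3374 shared) and 15 lists. Arrays of the same number had opposite dye orientation, so the correlations between them (-0.121, -0.0628, -0.2 and -0.0754, not adjusted for dye) cannot show whether the numbers pair the arrays. A slide block does not apply, since slide follows age, and each age modelled alone gives no test of the difference. Signal over background sets what can be measured, with 61.2% to 68.2% of spots per channel well above it.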

Other observations

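All tests of explanations in this part were chosen after the result they address was seen. In the circadian clock list the called members went both ways at 6 weeks. Lower were Hlf at -1.75 ± 0.17 (adjusted p = 0.00172), Dbp at -1.38 ± 0.24 (adjusted p = 0.0114), Tef at -0.96 ± 0.09 (adjusted p = 0.00172) and Ciart. Nfil3 and Npas2 were among the members that were higher. The list had 3 of 18 members higher and 4 lower (4 and 5 adjusted over the list alone), a median of 0.07, a mean of -0.19 and a test direction of down (camera adjusted p = 0.923). At 11 months Cry2 was higher and Bhlhe40 (-1.34 ± 0.12, adjusted p = 0.000157), Nfil3 (-1.04 ± 0.10), Ciart and Hlf were lower. The counts were the same adjusted over the list alone (median -0.0035, camera adjusted p = 0.515). The difference between ages was positive in Dbp, Hlf, Tef and Per3 and negative in Bhlhe40, Nfil3 and Npas2, or 5 and 7 adjusted over the list alone (median -0.03, mean 0.06, test direction down, camera adjusted p = 0.768). Without 6-week-old array 1 the call of Dbp at 6 weeks ended (adjusted p = 0.0539). Median centring ended the 6-week-old calls of Dbp (-1.19, adjusted p = 0.133) and Tef (-0.71, adjusted p = 0.137), that of Hlf at 11 months (-0.48, adjusted p = 0.176) and the differences of Dbp and Hlf (adjusted p = 0.136 and 0.109). No dye coefficient ended the same differences (adjusted p = 0.0511 and 0.0657). The call of Hlf at 11 months ended without 11-month-old array 1, 2 or 3 (adjusted p = 0.0587 to 0.0821). The call of Hlf for the difference ended without 6-week-old array 1, 2 or 3 or 11-month-old array 1 or 2 (adjusted p = 0.0559 to 0.0762). The hour of tissue collection is not given in the sources used here.

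In the stress and amino acid list Psat1 stood at 2.06 ± 0.15 at 6 weeks (adjusted p = 0.000754) and 3.91 ± 0.15 at 11 months (adjusted p = 1.01e-05). Phgdh stood at -0.27 ± 0.18 at 6 weeks (adjusted p = 0.347) and 3.09 ± 0.18 at 11 months (adjusted p = 4e-05). Of the list 3 of 19 members were higher at 6 weeks (Psat1, Fgf21 and Atf4) and 2 lower (Cth and Shmt2), the same adjusted over the list alone (median -0.03, mean 0.08, test direction up, camera adjusted p = 0.938). At 11 months 7 were higher and 4 lower (Trib3, Ddit3, Shmt2 and Vldlr), the same adjusted over the list alone (median 0.04, camera adjusted p = 0.592). The difference was positive in Phgdh, Psat1 and Cth and negative in Atf4 and Ddit3, or 6 and 4 adjusted over the list alone (median 0.08, camera adjusted p = 0.547). The call of Atf4 ended without 6-week-old array 3 (adjusted p = 0.0524) and that of Trib3 without 11-month-old array 1 or 2 (adjusted p = 0.0645 and 0.0703). That of Fgf21 ended without 6-week-old array 1, 3 or 4 or 11-month-old array 2 (adjusted p = 0.0513 to 0.101).

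In the chaperone list 3 of 21 members were higher at 6 weeks (Dnajb9, Canx and Dnajc3) and 2 lower (Hspb1 and Sdf2l1), or 3 and 4 adjusted over the list alone (median 0.00018, camera adjusted p = 0.928). At 11 months Xbp1 rose by 2.02 ± 0.25 (adjusted p = 0.000777). In all, 11 members were higher and 3 lower (Hspe1, Hspd1 and Herpud1), or 12 and 3 (median 0.27, camera adjusted p = 0.0363; adjusted p = 0.558 with an estimated correlation). That call ended without 6-week-old array 1 or 2 or 11-month-old array 3 (adjusted p = 0.0531, 0.0532 and 0.134), and with each age modelled alone (0.0591). The difference was positive in 8 and negative in 2 (Hspd1 and Hspe1), or 9 and 3 (median 0.27, camera adjusted p = 0.0732, and 0.0123 without 11-month-old array 4). It also passed with the scanner software's log ratio (0.0483), no filter on dim probes (0.0309) and the replicate block (0.0477). The call of Dnajb9 ended without 6-week-old array 2 or 3 (adjusted p = 0.0618 and 0.0915).

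Cell cycle genes rose at 11 months in 8 of 15 members, 11 adjusted over the list alone (median 0.35, camera adjusted p = 0.00154; adjusted p = 0.173 with an estimated correlation), with Mki67 at 0.83 ± 0.13 (adjusted p = 0.00241). At 6 weeks Ccnb2 was higher and Rrm2 lower, or 2 and 2 adjusted over the list alone (median 0.06, camera adjusted p = 0.758). The difference was positive in 5 (Ube2c, Rrm2, Birc5, Pcna and Mcm5), the same adjusted over the list alone (median 0.24, camera adjusted p = 0.0109; adjusted p = 0.281 with an estimated correlation).

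Immediate-early genes respond within minutes to handling of tissue. Of 19 members 2 were higher at 6 weeks (Ier3 and Ier2), 1 adjusted over the list alone (median 0.25, camera adjusted p = 0.0976). The list passed without 6-week-old array 1 or 4 or 11-month-old array 4 (adjusted p = 0.00976, 0.0255 and 0.048), with no filter on dim probes (0.0424) and with each age modelled alone (0.0321). The call of Ier3 ended without 6-week-old array 1, 2 or 3 or 11-month-old array 2 or 3 (adjusted p = 0.0558 to 0.135). At 11 months 3 were higher (Egr2, Socs3 and Myc) and 2 lower (Nr4a2 and Dusp1), or 1 and 2 adjusted over the list alone (median -0.11, camera adjusted p = 0.834). The difference was positive in 2 (Egr2 and Myc) and negative in 4 (Ier3, Nr4a2, Dusp1 and Ier2), the same adjusted over the list alone (median -0.61, camera adjusted p = 0.142). It passed without 6-week-old array 1 or 4 or 11-month-old array 3 (adjusted p = 0.0452, 0.0453 and 0.0269), with median centring (0.0481) and with the replicate block (0.0137).

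Among 29 partners of PRDM16 and adipose regulators 2 were higher at 6 weeks (Nrip1 and Tle3) and 2 lower (Ppargc1b and Twist1), the same adjusted over the list alone (median 0.0050, mean 0.0098, test direction down, camera adjusted p = 0.928). At 11 months 4 were higher (Nrip1, Zfp423, Tle3 and Rxra) and 4 lower (Ppargc1b, Esrra, Cebpb and Hlx), the same adjusted over the list alone (median -0.03, camera adjusted p = 0.621). Other kept probes of Zfp423 were not called (0.40 and 0.25, adjusted p = 0.0857 and 0.179 in a limma model of all kept probes). Ppargc1b stood at -1.76 ± 0.14 (adjusted p = 0.000121) and the Prdm16-related gene Mecom at 0.036 ± 0.06 (adjusted p = 0.692, and 0.83 with adjusted p = 0.0435 by the scanner software's log ratio). The difference was negative in 3 (Cebpb, Ppargc1b and Esrra), the same adjusted over the list alone (median 0.06, mean -0.02, test direction down, camera adjusted p = 0.801). Single arrays ended the 6-week-old calls of Nrip1 and Twist1 (6-week-old array 1, 2 or 3, adjusted p = 0.0583 to 0.0956). They also ended the differences of Cebpb (11-month-old array 1, adjusted p = 0.0517) and Ppargc1b (6-week-old array 2 or 4 or 11-month-old array 1, 2 or 3, adjusted p = 0.0516 to 0.0626).

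Nerve and Schwann cell genes had 1 of 14 members higher at 6 weeks (Pmp22) and 2 lower (Prx and Ncmap), or 3 and 3 adjusted over the list alone (median -0.011, camera adjusted p = 0.979). At 11 months Pmp22 was higher and S100b and Th lower, the same adjusted over the list alone (median 0.03, mean -0.02, test direction up, camera adjusted p = 0.965). The difference was positive in Prx and Ncmap and negative in Th, the same adjusted over the list alone (median 0.03, camera adjusted p = 0.808). The 6-week-old calls of Pmp22 (6-week-old array 1 or 3), Prx (6-week-old array 2, 3 or 4 or 11-month-old array 1, 2 or 3) and Ncmap (6-week-old array 3 or 4) ended without single arrays (adjusted p = 0.0506 to 0.107). Of 9 erythrocyte genes Bpgm was lower at both ages, the same adjusted over the list alone (medians -0.16 and 0.09, camera adjusted p = 0.176 and 0.834). The difference was past the limma test in 0 of them, with 0 at an unadjusted p under 0.05 (median 0.31, camera adjusted p = 0.199, fry adjusted p = 0.323). Without 6-week-old array 1 the erythrocyte list passed at 6 weeks (adjusted p = 0.00234) and for the difference (adjusted p = 0.0148), and for the difference also with the replicate block (adjusted p = 0.0411). Of 9 skin and epithelium genes Krt10 was higher at 6 weeks, the same adjusted over the list alone (median -0.011, mean 0.0060, test direction up, camera adjusted p = 0.912). By limma 0 passed at 11 months, with 0 at an unadjusted p under 0.05 (median -0.11, camera adjusted p = 0.503, fry adjusted p = 0.121). By the same test 0 passed for the difference, with 3 at an unadjusted p under 0.05 (median -0.08, camera adjusted p = 0.278, fry adjusted p = 0.101).

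Of 3 sex-linked genes 0 passed the limma test at 6 weeks, with 1 at an unadjusted p under 0.05 and 1 past the test adjusted over the list alone (median 0.03, camera adjusted p = 0.603, fry adjusted p = 0.238). At 11 months Eif2s3y was lower (-0.70 ± 0.05, adjusted p = 9.31e-05), the same adjusted over the list alone (median 0.03, mean -0.20, test direction down, camera adjusted p = 0.592). Its difference was negative (list median -0.15, camera adjusted p = 0.174). More males among the 11-month-old wild-type animals are argued against by Ddx3y (0.03) and Uty (0.07), whose lower 95% bounds were no lower than -0.0995. The X-linked copy Eif2s3x stood at -0.75, and the Eif2s3y probe may read it. Ddx3y, Uty and Eif2s3x were chosen after their values were seen.

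Whether genes within 10 Mb of the Prdm16 probe changed more often was tested as a sign of a passenger region around the targeted gene. At 6 weeks 39 of 202 such genes changed (19.3%, against 16.2% of other genes; odds ratio 1.23, 95% interval 0.846 to 1.76, Fisher's exact test p = 0.25). At 11 months 66 of 202 changed (32.7%, against 34.8%; odds ratio 0.909, 95% interval 0.666 to 1.23, exact p = 0.553). Both intervals lie under an odds ratio of 2, but Fisher's test takes genes as independent. Genes of the same arrays are correlated, so the intervals may be too narrow, and an excess near the gene stays open.

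The counts of genes were set against other assignments of the arrays. At 6 weeks 1 of the 8 assignments of genotype to channels, the real one, gave as many genes (3520, highest other 0). At 11 months 1 of 8 did (7544, highest other 1). These 8 assignments are too few for a share under 0.05. For the difference between ages 1 of the 35 splits of the 8 arrays, the real one, gave as many genes (3952), and the highest other was 35, for the split that follows the dye. That share is under 0.05 and is the lowest that 35 splits can give. The splits include ones that are not balanced for dye as the real one is, so the share does not exclude chance. Batch is not excluded either, because it follows age.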
